A study of Mus musculus with 2 samples.

How the data were processed

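PolyA-selected RNA was measured in immortalised monoclonal lines of adult murine mesenchymal stem cells, also described as fibroblasts in the labels. A line with floxed, intact Dicer alleles (wild type, WT) was compared with a line lacking Dicer (knockout, KO). The labels give 1 sample per genotype. Cells were lysed below confluence, and libraries were made with an Illumina TruSeq kit for paired reads of 50 bases, per the labels' protocols.

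The authors deposited 1 table of their own WT and KO comparison, with 23227 gene symbols and no coordinates. The submitters' processing notes name TopHat 1.4.0, DESeq 1.10.1 and the mouse build mm9, without their role or order. The read counter and the gene annotation are not given in the sources used here. Per the file headers, the deposited table has the columns of a DESeq comparison of conditions A and B. A was read as WT and B as KO from the order of both names in the comparison's title and the tool's naming habit, never from the values, and every direction given here rests on that reading. The authors deposited, as a signal per gene, the mean read count after division by DESeq size factors, for each genotype and over both. The deposited fold is the ratio of KO over WT, and the deposited log2 value is its logarithm; both were recomputed from the means and differed by rounding error alone. The authors' p-values and adjusted p-values were copied and not recomputed. No reads were listed for 5924 symbols, which left 17303.

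The depth behind these means was read from the table itself. Each genotype's mean turned out to be a sum of whole multiples of 2 fixed steps, the signature of a mean over 2 libraries. For 100% of the 16386 genes above 0 in WT and of the 16350 genes above 0 in KO, exactly 1 pair of whole read numbers gave the deposited mean. Size factors recomputed from the recovered reads matched the steps. The 4 recovered libraries are called the deeper and the shallower WT or KO library after their totals. These names give only the rank of the total within a genotype, and totals were not matched between genotypes. The labels list 1 sample per genotype and say nothing on how these libraries relate, so they are not named as separate cultures, and the spread between them may be technical. Because the deposited columns are means, values are printed as the authors' mean with the values of both recovered libraries as the spread. The design fixed before the data were examined had assumed 1 library per genotype, also for the authors' p-values. It was kept as written, and tests between libraries are alternatives chosen after seeing the data.

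A gene was tested when its mean over both genotypes was at least 20 normalised reads, which kept 11710 genes. It was called higher or lower in KO when the ratio of means was at least 2 or at most 0.5 and its 95% exact (Clopper-Pearson) interval excluded 1. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. A genotype with 0 reads was set to a floor of 3 reads over its libraries for medians, and its fold is given as the bound of the counting interval nearest 1. For a single library, 3 reads equal between 2.76 and 3.36 normalised reads. The authors' adjusted p was read at a threshold of 0.1.

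Gene lists were fixed before the data were examined: small RNA machinery, published targets of let-7, miR-29, the miR-17 family, miR-21 and miR-15/16, imprinted genes, microRNA host transcripts, interferon response, p53 targets, cell cycle, lineage markers (mesenchymal stem cell, osteoblast, adipocyte, chondrocyte, smooth muscle), markers of other cell types (haematopoietic, endothelial, epithelial, pluripotent), TGF-beta and BMP response, inflammatory secreted genes, housekeeping genes, Y-linked and X-inactivation genes, Hox genes, ribosomal protein genes, histone genes and mitochondrially encoded genes. The median log2 ratio of a list was placed among 10000 random lists of the same size, matched in 20 bins of mean expression, and a list stood apart when it lay outside the central 95%. Lists with fewer than 5 tested members are given as values. For each list the authors' p-values were also adjusted over the list alone by the Benjamini-Hochberg method. Counts from the authors' table given for a list cover its tested members only. For 29 microRNA seed families, sites of 7 bases (complementary to seed positions 2 to 8) were searched in the longest annotated 3' UTR of each gene. UTR sequences came from GENCODE mouse release M21 on assembly GRCm38, which is not the authors' build and was used for sequence alone, with no coordinates. Symbols were matched for 22752 of 23227 genes (98.0%), 1915 of them through older symbols. Of the tested genes, 11337 (96.8%) had a 3' UTR. Random lists for seed families were matched on expression (5 bins) and UTR length (10 bins). Genes with 1 site and with 2 or more were later set against random lists matched in the same way, and list medians were later also taken in pairs of like depth (the deeper KO against the deeper WT library, the shallower against the shallower), both chosen after seeing the data.

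The genes named were set by rule: Dicer1, the 12 highest and 12 lowest ratios among 9894 genes with a mean of at least 100 (ranked by the interval bound nearest 1, with predicted genes skipped), up to 4 members of each list with the largest change, and the 5 most abundant genes of each genotype. No gene was skipped among the highest and 1 among the lowest. Genes outside this rule are said to be chosen after their values were seen. Single values of 2 genes, 1 of the housekeeping list and 1 of the liver list, are not reported here, though both count in the totals of their lists.

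Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1, were used. limma was run on log2 of the normalised reads of the 4 recovered libraries plus 1, with Benjamini-Hochberg adjustment at 0.05, as an alternative chosen after seeing the data. Its p-values measure only the spread between these libraries. With the pairing of libraries as a block, which was read from the same data, few residual degrees of freedom are left. Those p-values lean on the spread shared across genes. Scripts were tested on simulated reads for the KO against WT comparison. Both libraries' reads were recovered for 100% of 23227 simulated genes. With the spread at its median over 11710 genes, the size rule recovered 46.2% of genes changed by 2-fold and 100% of those changed by 4-fold, and called 0.0183% of unchanged genes. With the spread at its mean over 11710 genes these shares were 52.5%, 98.5% and 2.51%, with 11682 simulated genes past the filter. limma recovered 87.4% and 100% at the median spread and 15.0% and 90.5% at the mean spread. Each simulation gave all genes the same spread and no difference between deeper and shallower libraries shared by both genotypes. Its shares of changed and unchanged genes called therefore do not carry over to the real calls. Of 100 random lists of 20 genes, 3 stood apart with no shift and 100 with a shift of 0.5 on the log2 scale. The list test used the median spread and mostly unchanged genes, so its power does not carry over to the lists reported here. Matched random lists of the real data spanned -0.32 to 0.24 for 21 miR-29 targets and -0.59 to 0.60 for 5 adipocyte markers.

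Alternatives fixed before the data were examined were other filters on the mean, size rules of 1.5-fold and 4-fold, other scalings, a pseudocount of 10, no counting interval, stricter authors' thresholds, sites of 8 bases and matching on expression alone. Leaving out each recovered library, using only the deeper or only the shallower pair, requiring that libraries do not overlap, limma with and without a pairing of libraries, and regression on GC content and length were added later. Mitochondrially encoded genes were absent from the symbols used here.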

Results

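Messenger RNA of a Dicer-deficient (KO) line of adult murine mesenchymal stem cells was compared with that of a line with intact Dicer (WT). Dicer cuts microRNA precursors into mature microRNAs, and the comparison addressed how mature messenger RNA levels differed between the lines with and without it. The 2 WT libraries recovered from the authors' deposited table held 15369250 and 14135422 reads in genes, and the 2 KO libraries held 15718369 and 14969532. Between 15370 and 15705 genes were detected per library, and the 10 most abundant genes took 4.37% and 5.10% of the reads of the WT libraries and 3.57% and 3.44% of those of the KO libraries. Across tested genes, log2 values correlated with r = 0.958 between the WT libraries and 0.967 between the KO libraries, against 0.824 to 0.870 between genotypes, as a description across genes that are not independent replicates. Libraries of 1 genotype still differed by far more than counting noise (mean chi-square per gene of 63.1 in WT and 76.3 in KO, where counting noise gives about 1), with 8.73% of genes at least 2-fold apart in WT and 8.28% in KO. Values are given as the authors' mean normalised read count, followed where useful by those of the deeper and the shallower library.

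The targeted gene Dicer1 was lower in KO, with 565 normalised reads (573 and 557) against 873 in WT (804 and 943). The ratio was 0.647 with a counting interval from 0.60 to 0.698, so both KO libraries lay below both WT libraries, but the gene did not reach the 2-fold rule and its adjusted p was 0.497 in the authors' deposited table. A value per gene does not separate the deleted part of Dicer1 from the rest of the transcript, so the remaining reads say nothing on whether intact Dicer1 was made. Of the 13 genes of the small RNA machinery, 3 were higher, 1 was lower and 9 were neither. The authors' table called 2 higher and 0 lower, and 3 higher and 1 lower when adjusted over the list alone. Tnrc6a, a scaffold of the silencing complex, rose 3.01-fold from 1627 to 4898 (adjusted p = 2.78e-04 in the authors' deposited table). The Argonaute gene Eif2c2 (Ago2) rose 2.40-fold from 1929 to 4624 (adjusted p = 0.00744 in the authors' deposited table). Tnrc6b was 2.33-fold higher and Eif2c4, another Argonaute gene, 4.31-fold lower, with adjusted p = 0.114 and 0.173 in the authors' deposited table. The list's median log2 ratio of 0.03 lay among those of matched random lists (percentile 53.2). Drosha, Dgcr8 and Xpo5, which act upstream of Dicer and were picked out after their values were seen, had ratios of 1.29, 1.02 and 0.930, and those of Dgcr8 and Xpo5 lay on either side of 1 depending on the library left out.

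**Figure D1:**
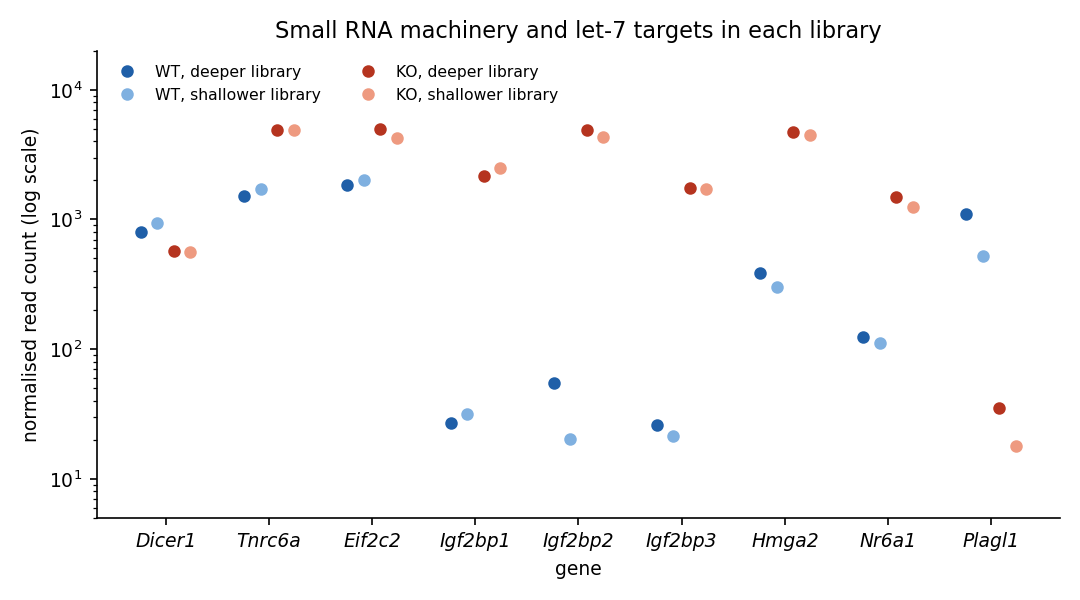
Normalised read count (log scale) of 9 genes of the small RNA machinery and of the let-7 target list in each of the 4 recovered libraries, with 1 point per library. Igf2bp1, Igf2bp2, Igf2bp3, Hmga2 and Nr6a1 lie above WT in both KO libraries, Plagl1 lies below, and Dicer1 differs by less than 2-fold.

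Large differences in both directions separated the lines. Of 11710 tested genes, 1044 (8.92%) were at least 2-fold higher in KO, 1002 (8.56%) were at least 2-fold lower and 9664 (82.5%) were neither. The authors' deposited table called 677 genes higher and 686 lower, of which 633 and 596 were among those called by the size rule. Both KO libraries lay above both WT libraries for 990 of the higher genes and below for 938 of the lower genes. Those genes had been picked by a ratio from the same libraries. Over all tested genes, both KO libraries lay above both WT libraries for 30.4% and below for 28.8%. Interchangeable libraries would give 16.7% each, but both genotypes shared a difference between their deeper and shallower library, described below. The median log2 ratio of tested genes was -0.01. limma on the 4 recovered libraries called 540 genes higher and 485 lower at an adjusted p of 0.05, against 1741 and 1658 at an unadjusted p under 0.05, and 2164 and 2077 at an adjusted p of 0.05 with the libraries paired by depth as a block, a pairing read from the data. Without the shallower WT library, 1104 genes were higher and 1062 lower, of which 880 and 860 were the same genes as with it.

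Among the 12 genes with the highest ratios were the oncofoetal RNA-binding protein genes Igf2bp1, Igf2bp2 and Igf2bp3. Igf2bp2 rose from 37.6 (54.9 and 20.2) to 4611 (4891 and 4332), a ratio of 123 with an interval from 97.8 to 156 (adjusted p = 1.44e-46 in the authors' deposited table). Igf2bp1 rose 80.0-fold to 2336 and Igf2bp3 rose 73.6-fold to 1743, with adjusted p = 8.78e-39 and 3.96e-36 in the authors' deposited table. Flrt2, a cell adhesion gene, had 1 read over both WT libraries and 550 normalised reads in KO, a ratio of 981 with an interval from 176 to 38777. Fam5c had 0 reads in WT and 206.3 normalised reads in KO, at least 108-fold higher. Msln (mesothelin) had 1 WT read and a ratio of 593 (106.04 to 23466), Muc13 had 2 and a ratio of 229 (63.0 to 1894), and the antiviral gene Rsad2 had 3 and a ratio of 190 (64.6 to 923). Mgat3, Lbp, Penk and the VEGF receptor gene Flt1 were 128-fold, 114-fold, 181-fold and 78.2-fold higher. All 12 passed the threshold in the authors' deposited table, with Penk the weakest at adjusted p = 0.0772. All 12 stayed far above 2-fold without each library, but the ratios of 9 moved by over 1.5 times. They were, without the shallower WT library, 297 for Msln, 94.9 for Rsad2, 90.5 for Penk, 74.9 for Mgat3, 49.8 for Flt1 and 884 for Lbp (WT libraries at 1.93 and 28.0), and without the deeper one 490 for Flrt2, 430 for Mgat3, 229 for Igf2bp2, 182 for Flt1 and 60.8 for Lbp. Ratios were 115 for Rsad2, 65.7 for Penk and 61.3 for Lbp without the deeper KO library, and 340 for Msln and 296 for Penk without the shallower one. The bound of Fam5c was 58.2 and 50.1 without the shallower and the deeper WT library.

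The 12 lowest genes included muscle and actin cytoskeleton genes. Cnn1 (calponin) was at 1809 (1173 and 2444) in WT and had 2 reads over both KO libraries, a ratio of 5.29e-04 (6.41e-05 to 0.00191). Fhl1 was 339-fold lower and Cap2 at least 126-fold lower. Dpysl3 fell from 2901 to 1.42 normalised reads, 3 reads in all, a ratio of 4.89e-04 (1.01e-04 to 0.00143; adjusted p = 3.69e-29 in the authors' deposited table). The fatty acid binding protein gene Fabp4 fell 803-fold from 1936 to 2.41 (adjusted p = 6.11e-55 in the authors' deposited table). The ephrin receptor gene Ephb2 had 1143 normalised reads in WT and 0 reads in KO, at least 646-fold lower (adjusted p = 5.15e-51 in the authors' deposited table). Cpxm2 and Fstl3 also had 0 reads in KO and were at least 117-fold and 114-fold lower. Stk39 had 2 KO reads and a ratio of 0.00266 (3.22e-04 to 0.00965), while Hhip and Kcnh1 had 1 read each and ratios of 0.00175 (4.41e-05 to 0.00977) and 0.00177 (4.48e-05 to 0.00992). Islr, at 1052 in WT (1904 and 201) with 2 reads in KO, missed the threshold in the authors' deposited table at adjusted p = 0.114, and the other 11 passed it. Of the 12, 9 moved by over 1.5 times with a library left out and all 12 stayed over 2-fold lower. Kcnh1 was 184-fold lower without the shallower WT library, Fhl1 219-fold, Cnn1 at a ratio of 8.16e-04 and Islr at 5.03e-04, and without the deeper one Kcnh1 was at 0.00106, Hhip at 0.00308 and Islr at 0.00477. Hhip was at 0.00349 without the shallower and Kcnh1 at 0.00355 without the deeper KO library. The bounds of Ephb2, Cap2, Cpxm2 and Fstl3 were 310-fold, 60.5-fold, 56.1-fold and 54.9-fold without the deeper KO library and 336-fold, 65.4-fold, 60.7-fold and 59.4-fold without the shallower one, and that of Cpxm2 was 61.9-fold and 179-fold without the shallower and the deeper WT library.

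**Figure D2:**
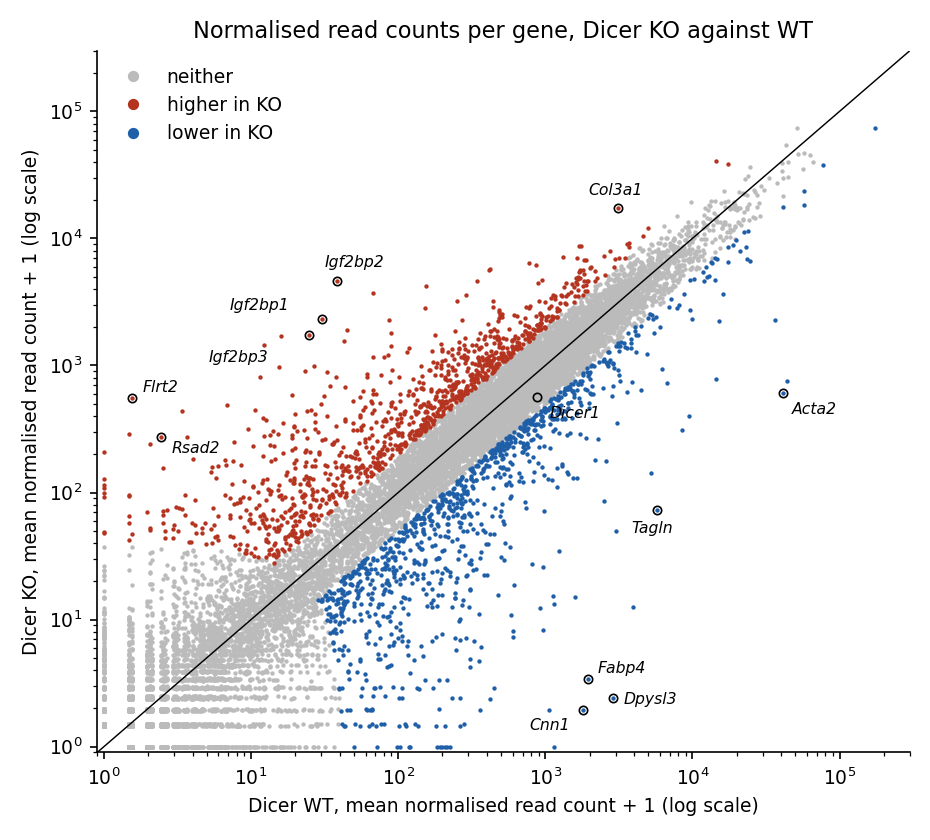
Mean normalised read count plus 1 of every gene with reads in WT (horizontal, log scale) and KO (vertical, log scale), with the line of equal values. Red points are the 1044 genes called higher in KO, blue points the 1002 called lower and grey points the rest, and circles mark 12 genes named in the text.

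Published targets of let-7, a microRNA family of differentiated cells, were higher in KO as a group. Of 29 tested members, 12 were higher, 1 was lower and 16 were neither, and the number lower was 3 without the shallower KO library and 2 without the deeper WT library. The authors' table called 11 higher and 1 lower over all genes, and 13 higher and 1 lower when adjusted over the list alone. The median log2 ratio was 0.79, above the range of matched random lists (-0.22 to 0.24, percentile 100), and 0.80 without the shallower WT library. Beside the Igf2bp genes, 2 members chosen after their values were seen led the list. The chromatin gene Hmga2 rose 13.4-fold from 345 to 4614 (adjusted p = 5.41e-19 in the authors' deposited table), and the nuclear receptor gene Nr6a1 rose 11.7-fold from 117 to 1367 (adjusted p = 9.62e-16 in the authors' deposited table). Plagl1, an imprinted zinc finger gene, went the other way and fell 30.6-fold from 808 (1096 and 519) to 26.4 (adjusted p = 0.00159 in the authors' deposited table).

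Published targets of miR-15/16 and of the miR-17 family were also higher in KO as groups. Of 12 tested targets of miR-15/16, 4 were higher, 1 was lower and 7 were neither, with a median of 0.83 (percentile 100). The authors' table called 3 higher and 1 lower, and 6 higher and 2 lower when adjusted over the list alone. The D-type cyclin genes Ccnd2 and Ccnd3, which drive entry into the cell cycle, rose 2.54-fold and 3.12-fold (adjusted p = 0.0360 and 2.52e-04 in the authors' deposited table), while Ccnd1 was 2.88-fold higher with KO libraries at 2231 and 6504 and did not pass. The growth factor receptor gene Fgfr1 fell 3.93-fold from 1648 to 420 (adjusted p = 8.49e-06 in the authors' deposited table). Of 16 miR-17 family targets, 2 were higher, 0 were lower and 14 were neither, with a median of 0.37 (percentile 98.1). The authors' table called 2 higher and 0 lower, over all genes and adjusted over the list alone, but not the same 2. Ccnd1, in this list as well as in that of miR-15/16, was higher by the size rule and did not pass in that table. The pro-apoptotic gene Bcl2l11 rose 6.88-fold from 143 to 982 (adjusted p = 2.01e-04 in the authors' deposited table). Without the deeper KO library this list no longer stood apart (median 0.29, percentile 96.0), and without the deeper WT library its median was 0.58. With libraries compared in pairs of like depth, its median was 0.25 in the deeper KO against the deeper WT library, not apart, and 0.54 in the shallower pair.

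Targets of miR-29 went both ways, with 6 of 21 higher, 6 lower and 9 neither, and the authors' table called 6 higher and 2 lower, or 7 higher and 3 lower when adjusted over the list alone. The collagen gene Col3a1 rose 5.58-fold from 3112 to 17363 (adjusted p = 3.49e-04 in the authors' deposited table). Col1a2, 1 of the 5 most abundant WT genes, fell 2.06-fold from 77682 to 37792 (adjusted p = 0.0419 in the authors' deposited table). The matrix enzyme genes Adamts9 and Loxl2 were 8.83-fold and 3.95-fold lower, and Col5a3 was 3.69-fold higher, but their libraries differed within a genotype (Adamts9 in WT at 2049 and 154), and none passed in the authors' table. In pairs of like depth Adamts9 was 10.3-fold and 3.03-fold lower and Loxl2 2.22-fold and 4.74-fold lower, with limma adjusted p = 0.0111 and 0.00860 with the pairing as a block against 0.305 and 0.249 without it. The pairing was read from these same libraries, so the blocked values are no independent support. The list's median of 0.50 (percentile 99.98) did not hold by library. It was 0.20 without the shallower WT library, -0.03 without the deeper KO library and -0.26 without the shallower KO library, none of which stood apart, and 0.30 without the deeper WT library (percentile 99.0). It was 0.19 in the deeper pair, not apart, and 0.35 in the shallower pair (percentile 99.8). Of 14 miR-21 targets, 3 were higher, 2 lower and 9 neither. The authors' table called 1 higher and 1 lower, and 2 higher and 1 lower when adjusted over the list alone. Tgfbi rose 3.73-fold and Tpm1 fell 3.69-fold (adjusted p = 0.0338 and 0.00131 in the authors' deposited table), Spry1 was 3.95-fold higher and Marcks 4.24-fold lower, and the median of -0.00 lay among those of random lists (percentile 48.6). Without the deeper KO library 1 was higher and 3 were lower.

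The same question was asked without published targets, from seed sites in 3' UTRs. The 1361 tested genes with a let-7 site had a median log2 ratio of 0.13, against -0.02 for genes without a site and 0.01 to 0.08 for random lists matched on expression and UTR length (percentile 100). The median was 0.12 for 1175 genes with 1 site and 0.24 for 186 genes with 2 or more, and 0.12 for the 1337 genes outside the published list. The median also rose with the number of sites in 8 of 9 families typical of other tissues, all but miR-223, but against lists matched on expression and UTR length the let-7 genes with 2 or more sites stood apart on the high side (percentile 99.98) and 0 of those 9 families did. Without the deeper KO library the medians of the let-7 and miR-17 families were 0.08 each and still stood apart (percentiles 99.99 and 100). Of genes with a let-7 site, 12.1% were at least 2-fold higher, against 8.60% of genes without. These shares were not matched on expression or UTR length and do not single out let-7. Of the 9 families typical of other tissues, all but miR-200b/c (8.50% against 9.13%) also had a larger share among genes with a site, such as miR-142-3p (11.1% against 8.85%). Among 20 families typical of fibroblasts, 10 stood apart and all of them on the high side. Beside let-7 these included miR-199a-3p, abundant in mesenchymal cells, at 0.15 over 1105 genes, and the miR-17 family at 0.13 over 1768 genes. The others were miR-26 (0.10), miR-143 (0.09), miR-15/16, miR-19, miR-27, miR-30 and miR-125 (0.08 each). The remaining 10, miR-21 and miR-29 among them, did not stand apart. With 2 or more sites, 4 of the 20 stood apart on the high side: let-7, the miR-17 family, miR-199a-3p and miR-23. Of these, miR-23 did not for genes with any site. The families miR-15/16, miR-19, miR-26, miR-27, miR-30, miR-125 and miR-143 did not stand apart with 2 or more sites. Of 9 families typical of other tissues, 1 stood apart, miR-302 at 0.08, whose seed overlaps that of the miR-17 family. Genes with a miR-302 site and no miR-17 site had a median of 0.04 (1137 genes, percentile 45.8). The calls of miR-19, miR-26, miR-125 and miR-143 were each lost when certain libraries were left out: the shallower WT library for miR-19 (0.09) and miR-125 (0.09), the deeper WT library (0.09), the shallower KO library (0.10) and the deeper KO library (0.06) for miR-26, the deeper KO library for miR-125 (0.03) and the shallower KO library for miR-143 (0.09). That of miR-302 was lost without the deeper WT library (0.09) or the shallower KO library (0.09). Without the deeper KO library, miR-143 and miR-302 kept theirs at 0.06 and 0.05. Conversely, miR-23 stood apart without the shallower WT library (0.11) or the deeper KO library (0.06), miR-21 without the deeper KO library (0.08), and miR-24 and miR-34 without the deeper WT library (0.10 each), all on the high side, and miR-122 did so on the low side without the deeper KO library (-0.02).

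**Figure D3:**
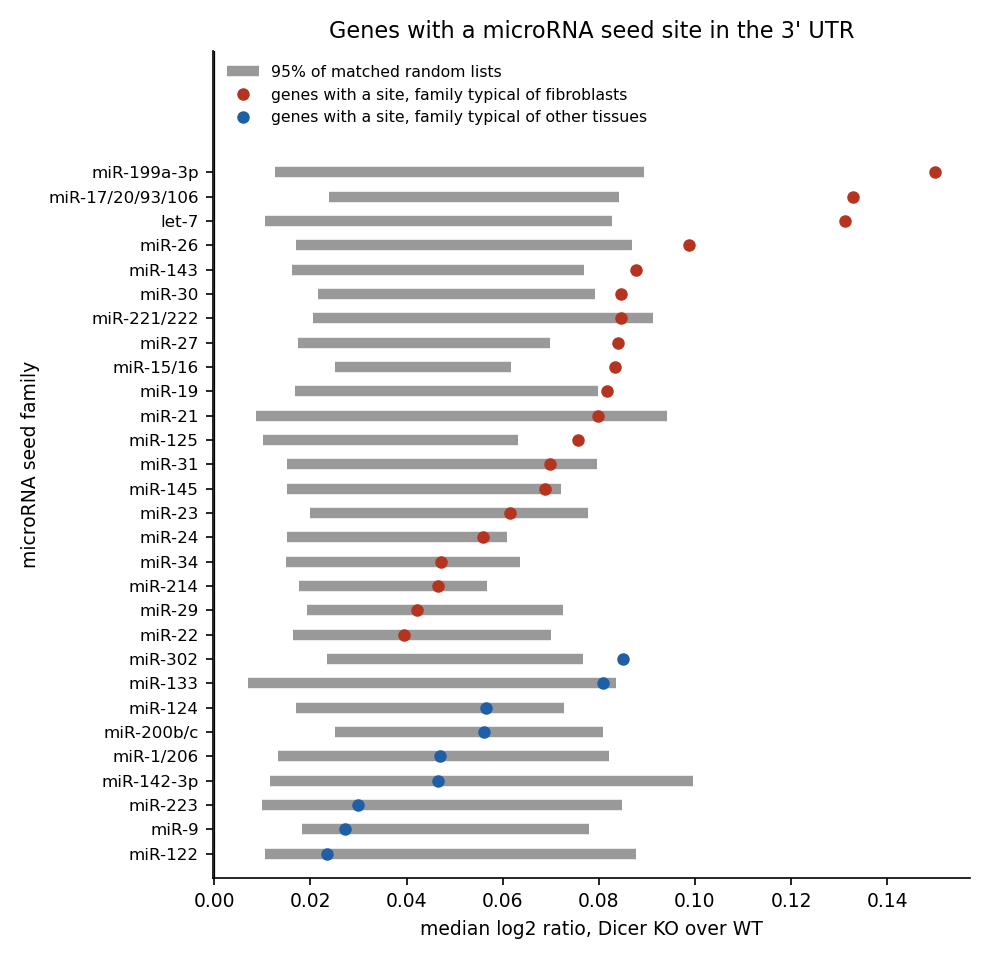
Median log2 ratio of KO over WT for tested genes with a seed site of each of 29 microRNA families, in red for 20 families typical of fibroblasts and in blue for 9 typical of other tissues. Grey bars span 95% of 10000 random gene lists matched on expression and 3' UTR length, and 10 red points and 1 blue point lie to the right of their bars.

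Contractile genes of smooth muscle cells and myofibroblasts were lower in KO. Of 11 tested members, 0 were higher, 8 were lower and 3 were neither, and the authors' table called the same numbers over all genes and adjusted over the list alone. The median log2 ratio was -2.71 (percentile 0), and -2.72 without the shallower WT library. Smooth muscle actin Acta2 fell 67.8-fold from 41324 (31371 and 51277) to 610 (579 and 640; adjusted p = 3.88e-10 in the authors' deposited table). Transgelin (Tagln) fell 79.2-fold from 5723 to 72.3 and the myosin light chain gene Myl9 fell 37.4-fold from 5256 to 140 (adjusted p = 0.00484 and 4.08e-09 in the authors' deposited table). Cnn1, described above, is the list's lowest member.

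Markers of mesenchymal lineages other than muscle were mixed. Of 8 tested osteoblast markers, 3 were higher, 4 were lower and 1 was neither, with a median of -1.76 (percentile 0.01), and -3.50 and -2.55 over the members with a mean of at least 5 and 100. The authors' table called 1 higher and 4 lower, and 1 higher and 5 lower when adjusted over the list alone. The bone transcription factor genes Sp7 and Msx2 fell 81.3-fold and 79.3-fold (adjusted p = 0.0849 and 3.04e-16 in the authors' deposited table). Alkaline phosphatase (Alpl) fell 18.5-fold from 14536 (21410 and 7662) to 785 (adjusted p = 0.0836 in the authors' deposited table). The osteocyte gene Dmp1 had 2 WT reads and KO libraries at 92.0 and 6.97, a ratio of 47.5 (12.8 to 397), and did not pass in the authors' table (adjusted p = 0.577). Of 5 adipocyte markers, 1 was higher, 3 were lower and 1 was neither, and the authors' table called 1 higher and 1 lower, also adjusted over the list alone. Beside Fabp4, lipoprotein lipase (Lpl) and the transcription factor gene Cebpa were 4.23-fold and 3.47-fold lower without passing, and Cebpb rose 2.88-fold (adjusted p = 0.0142 in the authors' deposited table). The median of -1.79 became -0.57 without the deeper WT library, in which Lpl stood at 16197 against 3551 in the shallower one, and the list then no longer stood apart, with 1 member lower. It was -2.48 and -2.65 without the shallower WT and the deeper KO library, and -1.90 and -1.17 in the deeper and the shallower pair, apart in both.

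Of 6 tested chondrocyte markers, 2 were higher and 4 were lower. Of these 6, the authors' table called 2 higher and 0 lower, and 2 higher and 3 lower when adjusted over the list alone. Acan, under the expression filter and picked out after its values were seen, had a deposited fold of 0. It was called lower (adjusted p = 0.0145 in the authors' deposited table). The cartilage transcription factor genes Sox9 and Sox5 rose 4.67-fold and 5.18-fold (adjusted p = 0.0712 and 0.00364 in the authors' deposited table). Collagen X (Col10a1) was 63.7-fold lower, with WT libraries at 275 and 28.0, and matrilin Matn3 was 4.93-fold lower, without passing. The median of -1.74 (percentile 0.17) was -0.86 without the deeper WT library and then no longer stood apart, and was -2.77 and -1.06 without the deeper and the shallower KO library. It was -1.58 in the deeper pair and -1.96 in the shallower pair, apart in both. General mesenchymal stem cell markers differed little: 1 of 13 was higher, 0 were lower and 12 were neither (median 0.09, percentile 74.2), with the same 1 gene and 0 genes in the authors' table over all genes and over the list alone. Without the deeper WT library 3 were higher and without the deeper KO library 2, and 1 was lower without the shallower WT or the shallower KO library. That gene, the adhesion receptor gene Vcam1, rose 2.81-fold from 1269 to 3568 (adjusted p = 0.0849 in the authors' deposited table). Lepr was 1.88-fold higher, and Vim and Eng had ratios of 0.689 and 0.701.

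**Figure D4:**
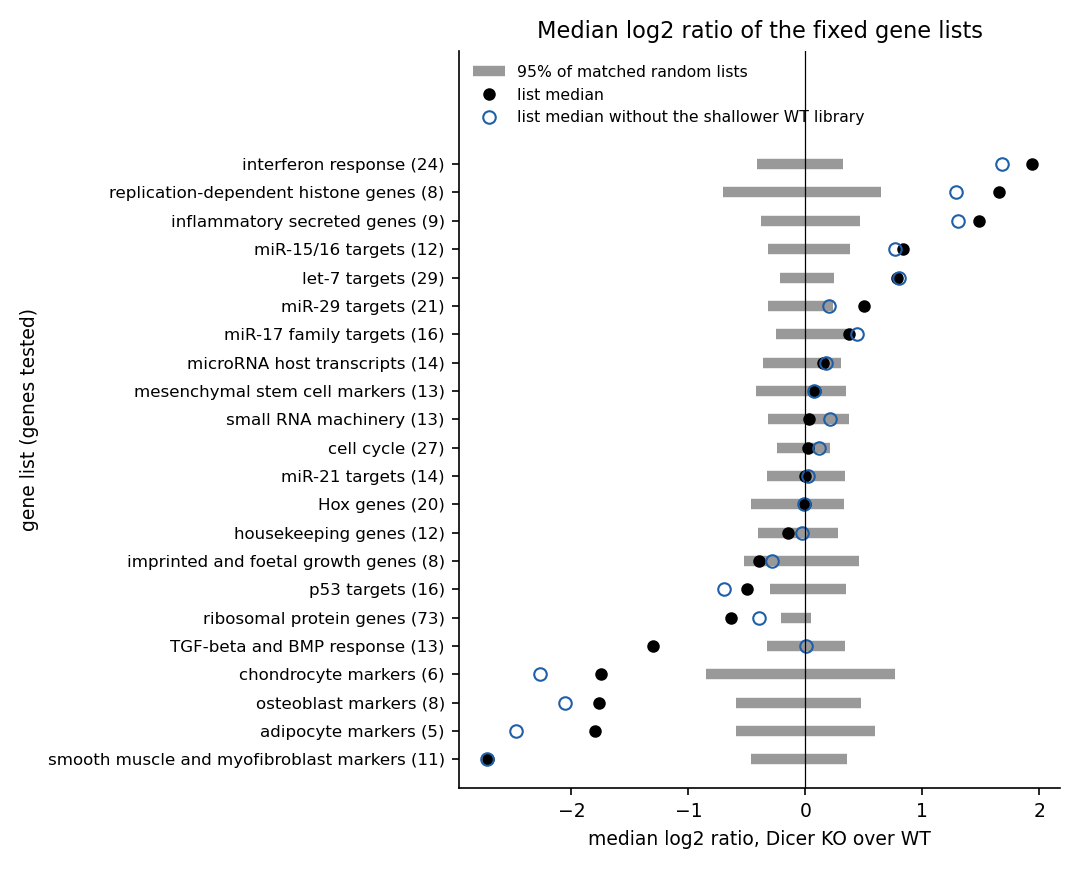
Median log2 ratio of KO over WT for each fixed gene list with at least 5 tested members (black points, number tested in brackets), with grey bars spanning 95% of 10000 random lists matched on expression. Open blue circles are the medians without the shallower WT library; interferon response genes lie farthest to the right at 1.94 and smooth muscle markers farthest to the left at -2.71, and the TGF-beta and BMP list moves from -1.30 to 0.01.

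Interferon response genes were higher in KO. Of 24 tested members, 16 were higher, 0 were lower and 8 were neither, with a median log2 ratio of 1.94 (percentile 100, random lists -0.41 to 0.32). The median was 1.31 without the deeper KO library and 1.13 over the members with a mean of at least 100, with a percentile of 100 in both cases. The authors' table called 11 higher and 0 lower, and 17 higher and 1 lower when adjusted over the list alone. Beside Rsad2, the antiviral genes Oas1a and Zbp1 rose from 1.04 to 51.1 and from 2.16 to 48.9 normalised reads (adjusted p = 2.30e-05 and 2.48e-04 in the authors' deposited table). Ifi44 rose 33.0-fold from 4.34 to 143 (211 and 75.6; adjusted p = 0.0520 in the authors' deposited table). WT levels of these 4 genes rested on between 2 and 9 reads, so their folds are imprecise.

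Of 9 inflammatory secreted genes, 6 were higher, 0 were lower and 3 were neither, with a median of 1.48 (percentile 100), or 0.76 without the shallower KO library (percentile 99.6). It was 0.36 in the deeper pair, where 3 were higher and the list did not stand apart (percentile 90.7), and 2.29 in the shallower pair. The chemokine gene Cxcl1 rose 3.86-fold (adjusted p = 3.06e-05 in the authors' deposited table). It was the list's only tested gene called in that table, which called 3 higher and 0 lower when adjusted over the list alone. The collagenase gene Mmp13 was 8.33-fold higher, Ccl2 5.04-fold and the prostaglandin synthase gene Ptgs2 3.14-fold, with libraries that differed within a genotype (Mmp13 in WT at 515 and 28.0, Ccl2 in KO at 854 and 4212). Of 16 p53 targets, 3 were higher, 4 were lower and 9 were neither, and the authors' table called 0 higher and 2 lower, or 1 higher and 2 lower when adjusted over the list alone. Eda2r and the pro-apoptotic gene Pmaip1 were 7.51-fold and 3.06-fold lower and Gadd45a and Sesn2 3.08-fold and 2.28-fold higher, and none of these 4 passed in the authors' table. The median of -0.50 (percentile 0.12) was -0.07 without the deeper WT library, no longer apart, and -0.58 and -0.33 in the deeper and the shallower pair, apart in both. The counts moved with the libraries: 1 was higher and 6 lower without the shallower WT library, 6 and 2 without the deeper WT library, 1 and 5 without the deeper KO library and 4 and 5 without the shallower KO library.

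Cell cycle genes differed little. None of 27 tested members was at least 2-fold higher or lower, 0 were called in the authors' table either over all genes or adjusted over the list alone, and the median was 0.02 (percentile 64.6). The largest differences were those of Ccne1 (ratio 1.80, interval 1.64 to 1.98), Pcna (1.43), Ccnb2 (0.709) and Birc5 (0.730).

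Of 13 genes responsive to TGF-beta or BMP, 1 was higher, 7 were lower and 5 were neither, with a median of -1.30 (percentile 0). Without the shallower WT library 3 were higher and 4 lower, and the median was 0.01 (percentile 36.4). That comparison sets the deeper WT library against both KO libraries. Deeper and shallower libraries differed in a way that both genotypes shared, described below. In pairs of like depth the list stood apart on the low side both times. It was at -0.68 in the deeper pair (percentile 0.04, with 2 higher and 6 lower). In the shallower pair it was at -1.21 (percentile 0, with 1 higher and 7 lower). The connective tissue growth factor gene Ctgf was at 1859 in the deeper and 28671 in the shallower WT library and at 672 and 3826 in the KO libraries, lower in KO in both pairs, and its ratio of 0.147 became 1.21 without the shallower WT library. The matricellular gene Postn was 27.3-fold lower (12.3-fold without that library) and Ltbp2 fell 11.9-fold (adjusted p = 0.145 and 0.0531 in the authors' deposited table), and Tgfbi rose as given above. The authors' table called 1 higher and 1 lower, and 2 higher and 3 lower when adjusted over the list alone.

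Among 8 tested imprinted and foetal growth genes, 2 were higher, 3 were lower and 3 were neither (median -0.39, percentile 6.92). Without the deeper WT library the median was -0.61 and the list stood apart, as it did in the shallower pair (-0.67), and without the deeper KO library 1 was higher. The authors' table called 0 higher and 3 lower, and 1 higher and 3 lower when adjusted over the list alone. Beside Plagl1, the growth inhibitor genes Cdkn1c and Grb10 fell 9.77-fold and 5.27-fold (adjusted p = 0.00808 and 9.36e-09 in the authors' deposited table). Mest, a host transcript of a microRNA, was 9.02-fold higher, with KO libraries at 1010 and 183, and did not pass. It was the only 1 of 14 microRNA host transcripts that reached 2-fold, with 13 neither (median 0.15, percentile 84.3; 2 higher and 1 lower without the shallower KO library), and the authors' table called 0 of them over all genes and 0 adjusted over the list alone. Pank3, Pank1 and Wdr82 had ratios of 1.79, 1.44 and 0.636, with Pank1 1.12-fold lower without the deeper KO library. Of 20 Hox genes, which set position along the body and limbs, 1 was higher, 3 were lower and 16 were neither (median -0.01, percentile 62.1). The authors' table called 0 higher and 2 lower, over all genes and over the list alone. Hoxc13 and Hoxa13, of the most distal group, fell 18.1-fold and 8.90-fold (adjusted p = 0.0502 and 0.0543 in the authors' deposited table), Hoxc12 was 4.27-fold lower and Hoxa9 2.11-fold higher. The number of higher Hox genes was 2 without the deeper WT or the shallower KO library and 0 without the deeper KO library.

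Ribosomal protein genes were slightly lower in KO as a group. Of 73 tested members, 0 were higher, 14 were lower and 59 were neither, and 1 had a positive log2 ratio. The median was -0.64 (percentile 0, random lists -0.21 to 0.05), and -0.40 without the shallower WT library, -0.29 without the deeper KO library and -1.11 without the shallower KO library, all apart on the low side. The number of lower members was 7 without the shallower WT library, 24 without the deeper WT library, 5 without the deeper KO library and 50 without the shallower KO library. The authors' table called 0 higher and 11 lower, and 0 higher and 17 lower when adjusted over the list alone. Rps27l, Rps12, Rps25 and Rpl41 fell 3.57-fold, 2.72-fold, 2.72-fold and 2.70-fold (adjusted p = 2.37e-05, 0.0225, 0.0676 and 0.00354 in the authors' deposited table). Ribosomal protein genes have many pseudogenes of near-identical sequence, and how such reads were counted is not given in the sources used here, so single members are uncertain. The elongation factor gene Eef1a1, the most abundant gene in both lines, fell 2.35-fold from 174550 to 74279, and Rpsa fell 3.16-fold (adjusted p = 0.00918 and 9.79e-05 in the authors' deposited table). The other abundant genes Rps2, Actg1, Fn1, Thbs1, Hspa8 and Hsp90ab1 had ratios of 0.597, 0.713, 1.45, 1.27, 0.819 and 0.882, and Thbs1 was at 2.30 without the shallower WT library and 1.14-fold lower without the deeper one, while Hsp90ab1 was 1.14-fold and 1.07-fold higher without the shallower WT and the deeper KO library. Of 12 housekeeping genes, 0 were higher, 2 were lower and 10 were neither (median -0.15, percentile 28.0), and the authors' table called the same numbers over all genes and over the list alone. The number of lower genes was 1 without the shallower WT library, 3 without the shallower KO library and 0 without the deeper KO library. The lower genes were Rplp0 (2.42-fold) and B2m (2.08-fold; adjusted p = 0.00567 and 0.0425 in the authors' deposited table), and Ywhaz had a ratio of 1.51.

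Histone genes of the replication-dependent class, whose transcripts mostly lack a polyA tail, were higher in KO. Of 68 in the table, 8 passed the expression filter, 7 of these were higher, 0 were lower and 1 was neither, with a median of 1.66 (percentile 99.98), or 1.01 over the members with a mean of at least 5. The authors' table called 4 higher and 0 lower, and 6 higher and 0 lower when adjusted over the list alone. Hist2h3c1, Hist1h1d and Hist1h2bc rose 13.1-fold, 11.8-fold and 5.72-fold (adjusted p = 8.42e-04, 0.00141 and 4.69e-05 in the authors' deposited table), and Hist1h2bg was 3.89-fold higher. Near-identical copies in these clusters leave single members uncertain. Without the shallower WT library 4 were at least 2-fold higher and the median was 1.29.

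Few markers of other cell types passed the expression filter. Of the haematopoietic markers, Cd14, Cd68 and Coro1a passed the filter, at 123, 26.9 and 28.8 normalised reads in WT and ratios of 1.46, 1.08 and 1.08, and Cd68 was 1.15-fold lower without the deeper and Coro1a 1.02-fold lower without the shallower WT library. The endothelial marker Egfl7 was 2.66-fold lower and the epithelial keratin gene Krt8 had a ratio of 1.30 (0.889 to 1.92), which was 4.43 without the shallower WT library and 1.31-fold lower without the deeper one. None of these passed in the authors' table, where Egfl7 had an adjusted p of 0.235. Egfl7 was called over the list alone, but as the only tested endothelial marker its p of 0.0272 in that table was left unadjusted. Of 9 pluripotency markers, 0 passed the filter. Xist, the RNA of the inactive X chromosome, was at 16511 in WT and 23780 in KO, a ratio of 1.44, and no Y-linked gene passed the filter.

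Many single genes named above varied with the libraries. Of 94 genes that the rule names beside the 12 highest and 12 lowest, 68 differed by at least 2-fold, and 51 of these kept that difference without each library in turn. The other 17 fell under 2-fold or reversed. Those that did so without the shallower WT library were Ctgf (ratio 1.21), Loxl2 (1.39-fold lower), B2m (1.83-fold lower), Sesn2, Hoxa9 and Ccnd2 (1.64-fold, 1.78-fold and 1.99-fold higher), and without the deeper WT library Adamts9, Cebpa and Lpl (1.23-fold, 1.37-fold and 1.52-fold lower). Those without the shallower KO library were Col5a3 (1.25-fold lower), Pmaip1 (1.67-fold lower), Ccnd1 and Ccl2 (1.47-fold and 1.70-fold higher). Those without the deeper KO library were Eef1a1, B2m and Rplp0 (1.99-fold, 1.93-fold and 1.92-fold lower), Sesn2, Hoxa9, Tnrc6b and Spry1 (1.22-fold, 1.61-fold, 1.82-fold and 1.85-fold higher). Leaving out 1 library also unbalances the difference between deeper and shallower libraries that both genotypes shared, described below. In pairs of like depth all 17 kept their direction, and 9 were at least 2-fold apart in both pairs (Tnrc6b, Adamts9, Loxl2, Ccnd2, Lpl, Cebpa, Ctgf, Rplp0 and Eef1a1). limma called 13 of the 17 with the pairing as a block and 0 without it. As the pairing was read from these same libraries and leaves few residual degrees of freedom, the 13 calls are no independent support.

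Of the 51, 26 moved by over 1.5 times, and 4 of them by over 3 times (Mmp13, Col10a1, Dmp1 and Mest). Their folds were, without the shallower WT library, 130 for Sp7, 116 for Col10a1, 43.6 for Tagln, 12.3 for Postn, 11.5 for Eda2r, 7.21 for Ltbp2 and 6.42 for Marcks, all lower in KO, and 50.7 for Zbp1, 16.5 for Ifi44, 5.78 for Mest, 4.87 for Ptgs2, 4.39 for Mmp13, 2.95 for Sox9 and 2.48 for Cxcl1, all higher. Folds without the deeper WT library were 42.3 for Postn, 32.4 for Sp7, 19.6 for Plagl1, 11.8 for Col10a1, 10.2 for Hoxc13, 9.75 for Alpl, 5.62 for Hoxa13, 3.49 for Eda2r, 2.82 for Eif2c4, 2.59 for Hoxc12 and 2.06 for Marcks, lower in KO, and 80.6 for Mmp13, 20.5 for Mest, 14.5 for Zbp1, 11.2 for Sox9, 10.7 for Bcl2l11, 8.79 for Hist1h2bc and 8.74 for both Sox5 and Cxcl1, higher. Leaving out the shallower KO library gave 124 for Tagln, 52.3 for Sp7, 17.6 for Postn, 5.37 for Rps27l and 4.10 for Rps12, lower in KO, and 88.2 for Dmp1 and 15.3 for Mest, higher. Leaving out the deeper KO library gave 184 for Sp7, 60.5 for Postn and 28.0 for Alpl, lower in KO, and 17.4 for Ifi44, 6.68 for Dmp1, 4.54 for Mmp13 and 2.77 for Mest, higher.

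Transcripts typical of liver were present in all 4 libraries. A list of 35 liver genes, none in the lists above, was drawn up after high values of such genes were seen in the shallower WT library. These genes took 0.0700% and 0.217% of the reads of the deeper and the shallower WT library, and 0.109% and 0.168% of those of the KO libraries. Albumin (Alb) stood at 2708 and 11234.5 normalised reads in WT and at 4083 and 8605 in KO. Between genotypes, 1 of the 35 genes was called higher, 1 (Tat) lower and 33 neither, and the authors' table called 1 higher and 0 lower. Without the shallower WT library, 23 were called higher and 1 (Hp) lower, with Tat at a ratio of 1.39. The lists whose calls changed without the shallower WT library are those of miR-29 targets and of TGF-beta and BMP response, as given with each.

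**Figure D5:**
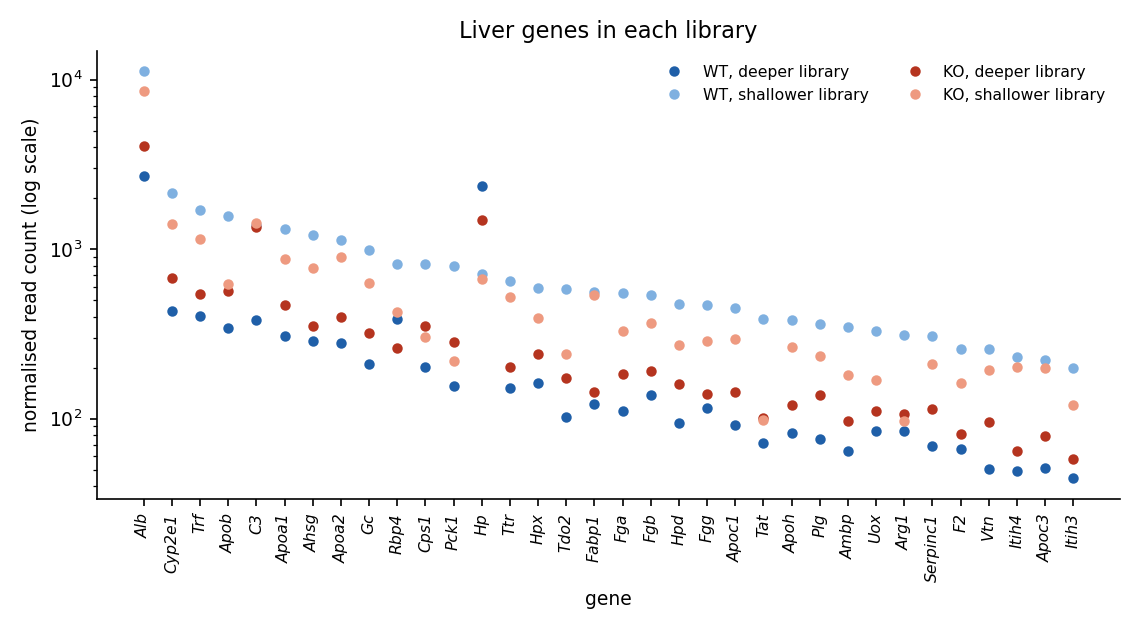
Normalised read count (log scale) of 34 genes of the list of 35 in each of the 4 recovered libraries, ordered by the value in the shallower WT library. The shallower WT library holds the highest value for 32 of the 34, with Hp and C3 as the exceptions, and the deeper WT library lies below the KO mean for 32.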

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

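The list of liver genes and the test of liver RNA in the shallower WT library were chosen only after the result was seen, and the reading of the test on the wild-type line was settled after its value was seen.

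Liver genes lie outside the comparisons of the report, yet all 35 had reads in all 4 libraries, and those outside large gene families were higher in the shallower than in the deeper WT library by a median of 2.10 on the log2 scale. Expression of liver genes by the WT line was argued against by the deeper WT library, which lay below the KO mean by a median log2 of -1.06 (quartiles -1.16 and -0.79, 33 of 35 genes below 0), where that explanation needs at least 1. The bound written beforehand against it also asked for the shallower library to lie over 2 above KO, which was wrong because the KO libraries hold liver transcripts too, and the value was 1.13. The KO mean mixes both KO libraries, and these genes were higher in the shallower than in the deeper KO library by a median log2 of 0.90. In pairs of like depth Alb was lower in WT in the deeper pair (2708 against 4083) and higher in the shallower pair (11234.5 against 8605). The test therefore speaks for the deeper WT library only. Reads shared within multigene families were argued against by the same 2.10 in genes outside such families, beside 2.86 in 15 family members. Liver RNA or reads that reached the libraries in unequal amounts, most in the shallower WT library, stay open as a candidate explanation. In that library 91.4% of the genes were highest, with Alb at 11234.5 against 2708, 4083 and 8605 normalised reads. The difference between the deeper and the shallower library shared by both genotypes, described below, ran the same way for these genes. It cannot be told apart from such unequal amounts. No biological explanation other than expression by the WT line was tested.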

How the results depend on the processing

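The alternatives with limma, with libraries left out or paired by depth and with GC content and length regressed out were chosen after seeing the data. Of all values recomputed under the alternatives, 521 stayed on the same side of their threshold or, for counts, within 1.5-fold. Another 27 gained a call, 25 lost one, 12 counts moved by over 1.5-fold and 1 reversed. The 521 include medians not standing apart that changed sign, such as that of microRNA host transcripts (0.15, or -0.14 without the deeper KO library). They also include the median-centred scaling, which subtracts the same constant from all genes and cannot change a percentile. Higher and lower genes numbered 2030 and 2092 at 1.5-fold, 392 and 391 at 4-fold, and the lower genes 622 at a mean of at least 100 and 1571 without a filter, as fewer or more genes could pass. limma called 540 higher and 485 lower, and 2164 and 2077 with libraries paired by depth as a block. This pairing was read from the data, and the cause was not tested. The authors' table held 365 and 369 genes at 0.01. Scaling to library totals gave 1135 and 926 genes and the upper quartile 982 and 1105, moving the median by 0.06 and -0.05. With 1 library left out at a time, higher genes ranged from 880 to 1342 and lower genes from 1062 to 1308. List medians ranged from -0.26 to 0.30 for miR-29 targets, reversed at -0.26 without the shallower KO library, from 0.29 to 0.58 for miR-17 targets, -0.70 to -0.0710 for p53 targets, -2.65 to -0.57 for adipocyte markers, -2.77 to -0.86 for chondrocyte markers, and -1.10 to 0.00678 for TGF-beta and BMP response. Seed medians ranged from 0.0609 to 0.119 for miR-19, 0.0580 to 0.110 for miR-26, 0.0321 to 0.111 for miR-125 and 0.0553 to 0.110 for miR-143. miR-19 also lost its call with a pseudocount of 10 (0.0774) and sites of 8 bases (0.0963), with which miR-302 (0.0890) lost its call too and miR-23 (0.122), miR-31 (0.116) and miR-124 (0.126, typical of other tissues) gained one. miR-125 lost its call at means of at least 5 (0.0510) and 100 (0.0869) and after regression on GC content and length (0.0404). miR-23 gained a call at a mean of at least 100 (0.0997) and after that regression (0.0609). The cause of these changes was not tested. In the deeper pair alone miR-29 targets (0.188), miR-17 targets (0.245) and inflammatory genes (0.362) lost their calls. Matching on expression alone, which leaves UTR length unbalanced, made 14 more families stand apart, 4 of them typical of other tissues (those of miR-1, miR-124, miR-133 and miR-200b/c). At a mean of at least 100 too few chondrocyte markers were left for a value. Folds against WT or KO levels of a few reads are limited by depth.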

Other observations

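The symbol families below, the tail used to pick them, the test of a shared unlabelled batch and the test of genes with 2 or more sites against matched lists were chosen only after the values were seen. The other tests on library differences and on let-7 sites were written before their results were seen.

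Semaphorin genes, which encode guidance signals for axons and vessels, were higher in KO as a family. Of 124 groups of at least 10 tested genes that share a symbol stem, 5 had a median in the outer 0.1% of matched random lists on either side, where 0.248 would by chance. Of 16 tested Sema genes, 7 were higher, 2 were lower and 7 were neither, and the authors' deposited table called 6 higher and 1 lower. Without the deeper WT or the deeper KO library 1 was lower. The median log2 ratio was 0.73 (percentile 99.94), and 0.82 without the shallower WT library. Sema3a rose 2.85-fold from 1828 (2592 and 1064) to 5219 (5143 and 5295), or 4.91-fold without the deeper WT library, Sema3g rose 10.8-fold and Sema4d 14.2-fold (adjusted p = 0.00113, 5.07e-06 and 9.42e-04 in the authors' deposited table). Sema5a rose 14.97-fold from 78.5 to 1175 (1672 and 679), or 8.64-fold without the deeper KO library (adjusted p = 0.0550 in the authors' deposited table). Sema6d fell 93.7-fold from 305 to 3.26 (7 reads in all), or 307-fold without the deeper and 55.3-fold without the shallower KO library (adjusted p = 9.99e-08 in the authors' deposited table).

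Tetraspanin genes, which encode membrane scaffolds, were lower in KO: 1 of 14 was higher, 6 were lower and 7 were neither, with a median of -0.85 (percentile 0.01), although the authors' deposited table called 1 higher and 2 lower. The median was -0.62 (percentile 0.46) without the deeper WT library and -0.81 (percentile 0.12) without the shallower KO library, both outside the tail used to pick families, and the number of higher genes was 2 in each case. Tspan7 and Tspan12 fell 16.3-fold and 8.70-fold and Tspan13 rose 17.4-fold (adjusted p = 2.17e-06, 1.53e-06 and 0.00129 in the authors' deposited table). Genes with the stem Cox, mostly nuclear-encoded subunits and assembly factors of cytochrome c oxidase, had a median of -0.49 (percentile 0.04), although 0 of 19 reached 2-fold and 0 were called in the authors' table. It was -0.24 (percentile 2.56) without the deeper KO library and -0.47 (percentile 0.12) without the deeper WT library, outside that tail, and 2 and 1 genes were lower without the shallower KO and the deeper WT library. Cox7a2 had the lowest ratio at 0.524 and Cox11 the highest at 1.55. The other families were Rpl (median -0.63) and Rps (-0.50, or -0.21 with percentile 1.24 without the deeper KO library), mostly the ribosomal protein genes described above.

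The difference between the deeper and the shallower library was shared by both genotypes. Across 11710 genes it correlated between WT and KO with Pearson's r = 0.571 and Spearman's rho = 0.609 (genes are not independent replicates), and 279 genes were at least 2-fold higher and 105 lower in the deeper library of both genotypes, against 21 in opposite directions. Examples picked after their values were seen are the immediate early gene Fos (752 and 41.5 in WT, 1745 and 257 in KO) and, the other way, Ctgf (1859 and 28671 in WT, 672 and 3826 in KO). GC content and transcript length were argued against, since r was 0.561 after regression on both, known for 99.2% of genes, which explained 3.04% of the variance in WT and 6.06% in KO. A shared batch or culture state, with r = 0.571 as its only value, cannot be told apart from other causes because the labels name no day, passage or preparation, and no biological explanation was tested.

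The upward shift of genes with a let-7 site was weighed against 3 explanations. UTR length and base composition were argued against, since the median's percentile was 100 after regression on UTR length, UTR GC content, transcript GC content and transcript length. Liver RNA in the shallower WT library was argued against as the sole source, since the percentile was 100 without that library. Leaving it out reverses the imbalance, with 0.0700% of reads in liver genes in the remaining WT library against 0.109% and 0.168% in KO. Without that library the let-7 median was 0.16. Without the deeper WT library, which left 0.217% in WT, the median was 0.13. Its sign held with liver reads in WT below and above those in KO, which argues against unequal liver RNA as the sole source. The hypothesis that these genes may be released from let-7 repression in KO was consistent with a median of 0.24 for genes with 2 or more sites, above lists matched on expression and UTR length (percentile 99.98), where 0 of 9 families typical of other tissues stood apart on the high side, and with 1 of these 9 standing apart for genes with any site. Of the 20 families typical of fibroblasts, 4 stood apart on the high side with 2 or more sites, let-7 among them. The rise of the median from -0.02 without a site over 0.12 with 1 site does not by itself single out let-7. In 8 of the 9 families typical of other tissues the median also rose from no site over 1 site to 2 or more. With matching on expression alone 5 of the 9 stood apart, past the bound of 3 written against release from repression. That setting leaves UTR length unbalanced, and 1 of the 9 stood apart after regression on length and GC content. With sites of 8 bases let-7 was at 0.12 (percentile 99.0), and 1 of the 9, miR-124, stood apart at 0.13 (percentile 98.4). With 1 monoclonal line per genotype, differences between the lines unrelated to Dicer were not tested and stay open.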
